A study of Homo sapiens with 6 samples.

How the data were processed

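RNA from A549 cells, an established human lung adenocarcinoma line, was sequenced after treatment with an siRNA against the long noncoding RNA SNHG17 (si-SNHG17, 3 libraries) or with a control siRNA (si-NC, 3 libraries). Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the Ion Total RNA-Seq Kit, and single-end reads were obtained on an Ion Proton sequencer. The labels name GRCh38 as the genome build, per the submitters' processing notes. The aligner, the counting tool, the annotation, the use of strand and any step that selected or depleted RNA are not given in the sources used here. Whether the read counting assigned or dropped reads shared between a gene and its copies is likewise not given, so values of the keratins, histones, ribosomal proteins, HLA genes, 7SL and U3 RNAs, and of overlapping or antisense genes, are uncertain to that extent.

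The authors deposited whole-number read counts per gene for 54261 genes and 6 libraries, not normalized, with a gene type beside each gene name. No gene name occurred more than once, and 24851 genes had no read in any library. Total counts ran from 8643076 to 12477214 per library. A count of 0 in a library allowed up to 3 counts, which was 0.240 to 0.347 CPM (counts scaled to a common library size of 1000000), an allowance for counting error only. No pair of libraries had identical values. A chi-square test of the counts gave 2.38 to 9.83 per degree of freedom within groups and 43.4 to 62.1 between groups, so all 6 libraries were counted as separate. The labels number the libraries within a group but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Groups and columns were taken from the titles. Gene positions came from the RefSeq annotation of GRCh38.p14, in which 45971 names matched by symbol and 1854 by a unique synonym.

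Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr, library sizes were scaled by TMM (factors 0.975 to 1.02), and si-SNHG17 was compared with si-NC by glmQLFit and glmQLFTest with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 15614 genes tested, with a threshold of 0.05. Log2 fold changes are si-SNHG17 minus si-NC, CPM values use the scaled library sizes, and errors are standard errors of the fit or standard deviations over 3 libraries. The log CPM values for SNHG17 were also compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1. The procedure was tested on simulated data for the comparison of si-SNHG17 against si-NC, with 200 changed genes among 15327 tested. It recovered 53.7% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 95.5% of those changed 4-fold. In that simulation 16 unchanged genes were called, which was 9.52% of the calls and above the 5% aimed at. It changed far fewer genes than the 6112 called in the data, so these shares need not hold for the real comparison.

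Before the data were examined, 23 gene lists were fixed, and those with at least 5 genes tested (20 lists) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the lists. The same test with an estimated correlation and the fry test were alternatives. A count adjusted over the list alone used the genes of that list as the family of tests. The genes named in the text were fixed by rule: SNHG17, then FOXA1, XAF1 and BIK, recalled as genes the study followed up, which was not checked here, and therefore treated as chosen on these samples. The 10 largest rises and the 10 largest falls were added, from genes with adjusted p under 0.05, a mean of at least 5 CPM, a gene symbol that was not a pseudogene, and no overlap of the groups. Up to 4 members of each list with the smallest p completed the rule; some genes it names are not reported here.

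Alternatives were other scalings (DESeq2 size factors, upper quartile, totals only), DESeq2 1.42.0, limma-voom, no filter or a mean CPM of at least 1, a 2-fold requirement, a replicate block, camera with an estimated correlation, fry, and leaving out each library. Alternatives added after the data were seen are named in the closing section, including an offset for GC content and transcript length fitted with mgcv 1.9.3. For the closing section, 3 prime UTRs of GENCODE release 29 were searched for 7-base sites in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The 16224 sites with at least 50 carriers among 11929 mRNAs were each compared with the remaining mRNAs, after a regression on UTR and transcript length and GC content. That search ranked the planted site first in 10 of 10 simulations in which carriers were lowered by 0.5 on the log2 scale. Fold changes were shuffled before planting. Each planted site had fewer carriers than the leading site of the closing section (2417 carriers, mean difference -0.225). The simulations therefore do not show how the search performs at that smaller shift, or where UTR composition tracks fold change. No sample or deposited column was left out.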

Results

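The series compared A549 cells treated with an siRNA against SNHG17 with cells given a control siRNA, to ask which transcripts change when this noncoding RNA is lowered; the series title places it in the proliferation and migration of non-small cell lung cancer. Each group had 3 libraries. The si-SNHG17 libraries held 9469557, 12477214 and 8643076 counts, and the si-NC libraries 8867818, 10246759 and 10978513. Within the si-NC group, replicate 3 differed from replicates 1 and 2 by 9.83 and 9.29 chi-square units per degree of freedom, against 2.38 between replicates 1 and 2. The first principal component, which held 63.9% of the variance, separated the groups. Mitochondrially encoded genes took 4.33% ± 0.187 of the counts in si-SNHG17 and 7.80% ± 0.470 in si-NC (SD, n = 3 each), and the 20 most abundant genes took 10.4% ± 0.0461 and 13.2% ± 0.0975.

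SNHG17, the targeted gene, was lower in each si-SNHG17 library. It lies on chromosome 20 from 38420588 to 38435328 (RefSeq, GRCh38.p14) and is annotated as a long noncoding RNA. It had 75, 105 and 99 counts in the si-SNHG17 libraries, or 7.82, 8.39 and 11.3 CPM, against 38.7, 36.2 and 51.4 CPM in the si-NC libraries. The means were 9.16 ± 1.86 CPM against 42.1 ± 8.16 CPM (SD, n = 3), which left 21.8% of the control level. The log2 fold change was -2.21 with a standard error of 0.167, and edgeR's quasi-likelihood test gave an adjusted p of 2.84e-07. The exact permutation test of log2 CPM gave p = 0.1, the smallest this design allows.

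FOXA1, XAF1 and BIK are recalled as genes the study followed up, which was not checked here, so they count as chosen on these samples and not as independent evidence. FOXA1, a forkhead transcription factor of airway and other epithelia, fell from 7.93 ± 0.720 CPM to 3.76 ± 1.06 CPM (log2 fold change -1.05, adjusted p = 0.0019 by edgeR). XAF1, an interferon-inducible antagonist of the caspase inhibitor XIAP, rose from 4.20 ± 1.19 to 21.2 ± 1.42 CPM (log2 fold change 2.32). BIK, a BH3-only promoter of apoptosis, rose from 6.97 ± 1.27 to 30.9 ± 1.05 CPM (log2 fold change 2.14). In all 3 the groups did not overlap.

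**Figure D1:**
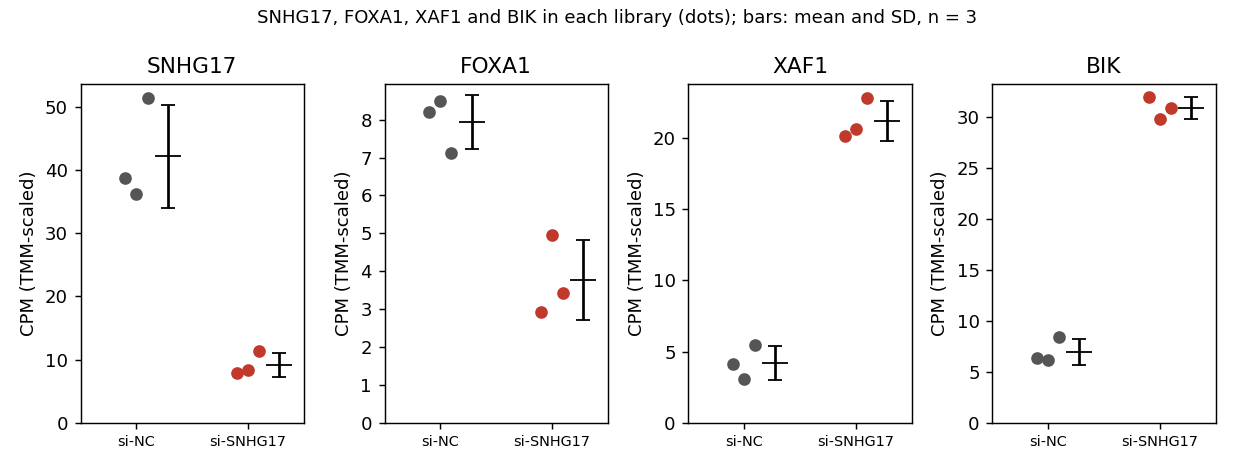
CPM of SNHG17, FOXA1, XAF1 and BIK in each library; dots are libraries, and the bars beside them are the mean and SD over 3 libraries. The SNHG17 mean was 9.16 CPM in si-SNHG17 and 42.1 CPM in si-NC.

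Across the transcriptome, 6112 of 15614 genes tested passed an adjusted p of 0.05 by edgeR, 3057 higher and 3055 lower in si-SNHG17. Of these, 1465 changed at least 2-fold, 697 upward and 768 downward. The groups did not overlap for 7713 genes (49.4%, where chance gives 10%). Among messenger RNAs 2805 rose and 2444 fell, of 12136 tested, and among long noncoding RNAs 75 rose and 259 fell, of 1022 tested. Leaving out si-NC replicate 3, which stood apart from its group, gave 6601 genes.

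The largest rises included small structured RNAs as well as messenger RNAs. RMRP, the RNA of RNase MRP, rose by 3.98 on the log2 scale (standard error 0.259), from 1.14 ± 0.452 to 17.9 ± 3.52 CPM. RN7SK, which restrains the elongation factor P-TEFb, rose by 3.49, and SNORD3A, the U3 RNA of ribosomal RNA processing, rose by 3.05 with a standard error of 0.338. Of messenger RNAs, the ammonium transporter RHCG rose from 23.9 ± 3.19 to 256.9 ± 19.9 CPM (log2 fold change 3.42). The activin subunit INHBA (3.40), the protease inhibitor PI3 (3.32), the sulfotransferase CHST2 (3.22), CRTAC1 (2.78), the splicing regulator PTBP2 (2.69) and the purine oxidase XDH (2.60) followed. The summed U1, U2, U4 and U5 snRNA rows, named after their values were seen, held 227 counts in the si-SNHG17 libraries and 11 in the si-NC libraries.

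CLDN2 had the largest fall among the genes the rule allowed. This tight junction gene fell from 75.2 ± 7.36 to 6.01 ± 1.27 CPM (log2 fold change -3.62, standard error 0.146), and ACLY, which makes cytosolic acetyl-CoA, fell from 1024 ± 69.2 to 143.1 ± 7.30 CPM (log2 fold change -2.84). SNX12 (-2.76), the anaphase-promoting complex subunit ANAPC13 (-2.68), the fibrinogen chain FGG (-2.67) and the ER lectin MLEC (-2.59) fell as well. The carbonic anhydrase CA12 (-2.58), the mucin MUC5AC (-2.52), the ER chaperone HYOU1 (-2.51) and the lysosomal protease CTSD (-2.43) completed the 10. The groups did not overlap for any of these 20 genes, which the rule required.

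**Figure D2:**
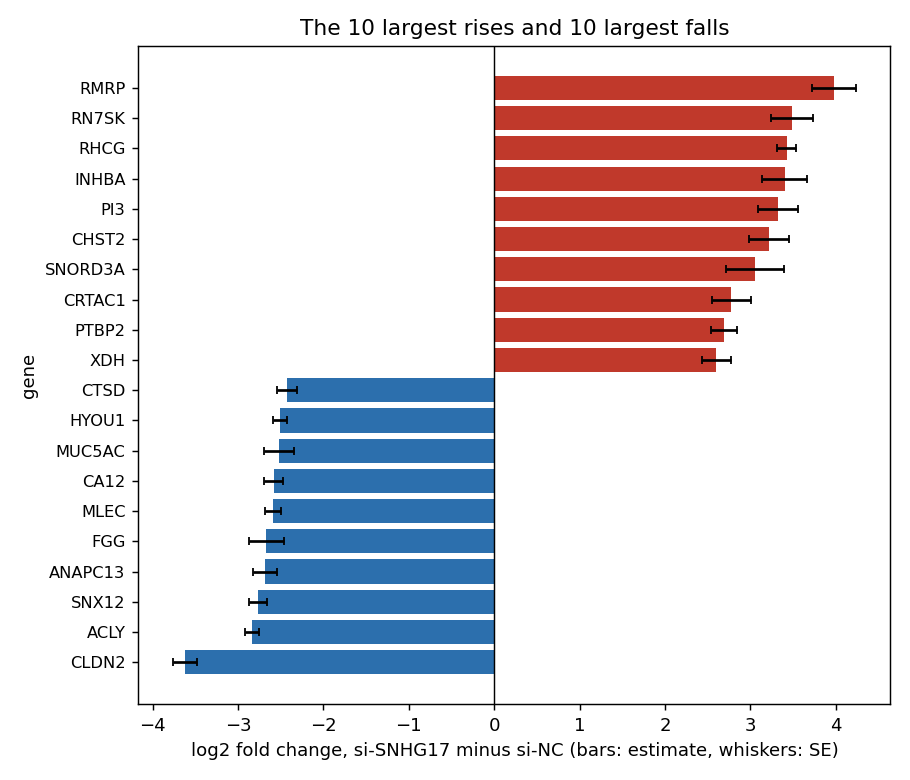
Log2 fold changes of the 10 largest rises and the 10 largest falls named by the rule, si-SNHG17 minus si-NC; bars are the fitted values and whiskers the standard error. RMRP had the largest rise (3.98) and CLDN2 the largest fall (-3.62).

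Cell cycle genes fell. Of 28 mitosis and G2/M genes tested, 25 fell and none rose, among them the kinesin KIF20A (-1.10), the chromosomal passenger protein BIRC5 (-1.33), the transcription factor FOXM1 (-1.04) and the cytokinesis protein PRC1 (-0.75). Of 30 DNA replication and G1/S genes, 25 fell and 2 rose, with GINS1 (-2.11), the helicase subunit MCM6 (-1.24), E2F1 (-1.64) and the ribonucleotide reductase subunit RRM2 (-1.38). Adjusted over the list alone, the counts were 25 and 26 falls. Camera gave adjusted p of 1.95e-13 and 1.72e-20, and both lists remained past the threshold with an estimated correlation (adjusted p = 0.021 for each).

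Of 23 p53 targets, 16 rose and 2 fell, with the smallest p for BTG2 (2.18), the stress-induced SESN1 (1.34), the cyclin CCNG1 (0.92) and the mitochondrial reductase FDXR (0.98). The camera adjusted p was 3.86e-11 and 0.021 with an estimated correlation. Adjusted over the list alone, 18 rose and 2 fell. Of 27 BCL2 family and apoptosis genes, 17 rose and 1 fell by both counts. They included BIK and XAF1, recalled as chosen by the study on these samples, so the list is not independent evidence of its direction, and the survival gene MCL1 (1.07), while the inhibitor BIRC5 fell. Camera gave an adjusted p of 9.81e-09, which was lost with an estimated correlation (adjusted p = 0.0754).

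At the preset correlation, the NF-kB list had the smallest adjusted p of the lists tested. Of 28 NF-kB and inflammatory genes, 26 rose and none fell, by both counts, with the antioxidant enzyme SOD2 (1.95) and the chemokines CCL20 (2.26), CXCL8 (1.91) and CXCL1 (1.44) at the smallest p. SOD2 went from 335.8 ± 29.8 to 1295 ± 17.7 CPM. Camera gave an adjusted p of 2.04e-40 and 0.021 with an estimated correlation. Of 33 interferon-stimulated genes, 24 rose and 1 fell, and 25 rose adjusted over the list alone. XAF1 (2.32), recalled as chosen by the study on these samples and so not independent evidence, was among them. So were IFIT3 (1.93), IFI27 (2.12) and HERC5 (1.40). Their camera adjusted p of 4.17e-13 was lost with an estimated correlation (adjusted p = 0.157).

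Migration genes rose more often than they fell, and epithelial and lineage genes went both ways. Of 26 mesenchymal and migration genes, 15 rose and 4 fell, by both counts, with LOXL2 (1.38), SERPINE2 (1.27) and the urokinase gene PLAU (1.09) among those that rose. The camera adjusted p was 0.000159 and 0.132 with an estimated correlation. Of 25 epithelial adhesion and junction genes, 9 fell and 6 rose, by both counts (camera adjusted p = 0.0732, but 0.0205 with no low-count filter and 0.0264 with the GC and length offset, and adjusted p = 0.157 with an estimated correlation). CLDN2, KRT18 (-0.93) and KRT8 (-0.75) fell and TJP3 (0.75) rose. Of 14 lung and airway lineage genes, 5 fell and 2 rose, by both counts. The secretory genes AGR2 (-1.70) and MUC5AC and the factor ETV5 (-0.95) fell, and LAMP3 rose (2.10). FOXA1, recalled as chosen by the study on these samples, is a member. The camera adjusted p of 0.0346 was lost with an estimated correlation (adjusted p = 0.132) and without si-SNHG17 replicate 3 (adjusted p = 0.0693), with limma-voom (0.191) and with robust dispersion (0.0687).

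Of 24 NRF2 targets, 11 fell and 2 rose, by both counts, including GCLM (-1.93), PGD (-1.88), AKR1B10 (-1.35) and GPX2 (-1.09), with camera adjusted p of 1.09e-06 and 0.0315 with an estimated correlation. Of 25 cholesterol synthesis genes, 16 fell and 1 rose (17 fell adjusted over the list alone), including IDI1 (-1.35) and HMGCS1 (-0.88), with adjusted p of 3.24e-07 and 0.021. Of 15 mitochondrially encoded genes, 13 fell and none rose, by both counts, with COX3 (-1.53), COX2 (-1.18), ATP6 (-1.16) and ND3 (-0.95) at the smallest p (adjusted p = 4.83e-19, and adjusted p = 0.0239 with an estimated correlation). They took 7.80% of the counts in si-NC and 4.33% in si-SNHG17. Of 28 hypoxia and glycolysis genes, 18 rose and 2 fell (3 fell adjusted over the list alone), such as P4HA2 (0.95), VEGFA (0.92), ALDOA (0.57) and HK2 (1.41), but the adjusted p of 0.000179 was lost with an estimated correlation (adjusted p = 0.224). Of 26 unfolded protein response and ATF4 genes, 9 rose and 8 fell (11 fell adjusted over the list alone). HYOU1 and PSAT1 (-1.82) fell, PPP1R15A (1.22) and ATF3 (1.51) rose, and the list did not pass (camera adjusted p = 0.391).

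Of 24 TGF-beta responsive genes, 12 rose (13 adjusted over the list alone) and 6 fell, with INHBA and ID3 (0.64) up and SMAD6 (-0.82) down (adjusted p = 0.0083, and 0.0754 with an estimated correlation and 0.085 without genes whose 3 prime UTR carries the 6-base sequence CTCTGT). Of 21 YAP/TAZ targets, 6 rose (7 adjusted over the list alone) and 5 fell, including F3 (1.81), GADD45A (0.74) and IGFBP3 (0.64) up and MYOF (-1.48) down, and the list did not pass (adjusted p = 0.794). Of 23 snoRNA host genes other than SNHG17, 11 rose and 4 fell, by both counts. C6orf48 (1.44), EPB41L4A-AS1 (1.43), GAS5 (0.93) and TAF1D (1.16) rose (adjusted p = 0.00196, lost with an estimated correlation at adjusted p = 0.307). None of the snoRNAs hosted by SNHG17 had enough counts to be tested.

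Genes near SNHG17 on chromosome 20 showed no shared direction. Of 14 such genes in the 20q11 list, 3 rose and 4 fell, by both counts, with FAM83D (-0.58) and RPN2 (-0.29) lower and SRC (0.30) and BLCAP (0.47) higher. The list did not pass (adjusted p = 0.813), and its median was -0.07 while its mean was 0.00. Of 36 ribosomal protein genes, 11 rose and none fell (6 rose adjusted over the list alone), with RPS28 (1.60), RPS27 (0.57), RPL13 (0.50) and RPL23 (0.32) at the smallest p, and the list did not pass (adjusted p = 0.0638), but it passed without si-SNHG17 replicate 1 (adjusted p = 0.0224), si-SNHG17 replicate 3 (0.0428) or si-NC replicate 3 (0.0023). It also passed with library totals only (0.038), limma-voom (0.0095), no low-count filter (0.0078) and the GC and length offset (0.0038), but not with an estimated correlation (adjusted p = 0.686). The size of the RPS28 rise depended on si-SNHG17 replicate 2. RPS28 had 17.8, 38.0 and 11.9 CPM in si-SNHG17 replicates 1 to 3, against 5.69, 7.59 and 9.27 CPM in si-NC. Of 9 replication-dependent histone genes, 6 rose and none fell, by both counts, with a median of 1.07. HIST1H1C (1.54), HIST1H2BC (1.54), HIST1H2BD (1.07) and HIST2H2BE (1.18) were among them, and the adjusted p was 0.000594 and 0.0516 with an estimated correlation.

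Markers of other cell types were few in this epithelial line. Of 19 immune cell markers, 4 had enough counts to be tested, and CD68 (1.37) and ITGAM (0.50) rose while CD14 (-0.88) fell. The ITGAM call was lost without si-SNHG17 replicate 2, si-NC replicate 1 or si-NC replicate 2 (adjusted p = 0.0816, 0.0743 and 0.0967 by edgeR) and with DESeq2 (adjusted p = 0.088). CD79A had a log2 fold change of 0.22 (standard error 0.492, not past the threshold). Of 18 stromal and endothelial markers, 3 were tested. THY1 fell (-0.49; adjusted p = 0.0571 without si-SNHG17 replicate 1 and 0.0674 without replicate 3), and ACTA2 (-0.15) and COL1A1 (0.06) did not pass. In all, 15 of 20 lists passed camera, 9 up and 6 down, and 7 with an estimated correlation. The same 15 passed fry, with the largest adjusted p for the snoRNA host genes (0.0139). The epithelial list passed fry too (adjusted p = 0.00081). The unfolded protein response (0.094), YAP/TAZ (0.521), 20q11 (0.453) and ribosomal protein (0.137) lists did not. Fry does not compare a list with the other genes, so it asks less than camera.

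**Figure D3:**
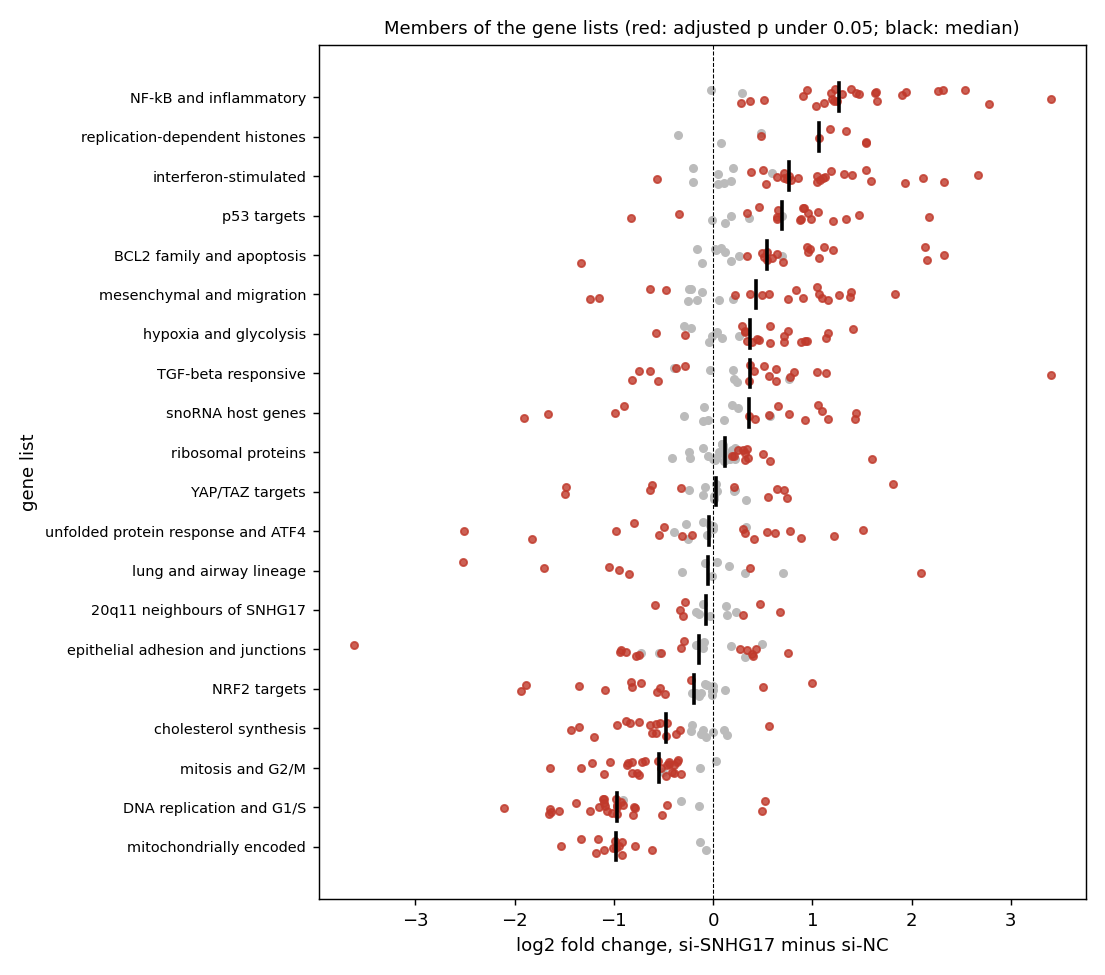
Log2 fold changes of the members of the 20 gene lists with at least 5 genes tested, ordered by median; each dot is a gene, red past an adjusted p of 0.05, and the black mark is the median. NF-kB and inflammatory genes had the highest median (1.27) and mitochondrially encoded genes the lowest (-0.98).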

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

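The robust fit, the restriction to mRNA and lncRNA, the GC and length offset, the settings without abundant genes, small RNAs or carriers of a 7-base site or its 6-base core were added after the data were seen; the rest were planned. SNHG17 was lower in every one of 21 alternatives, from -2.37 to -2.04 on the log2 scale with adjusted p no higher than 1.05e-05. Over the fits that left out each library, the genes past the threshold numbered 4911 to 6601 (the most without si-NC replicate 3), with 2473 to 3335 higher, 2438 to 3266 lower, and 15 to 16 lists. Requiring 2-fold left 1465 genes, 697 higher and 768 lower, by construction. Leaving out the carriers of the 6-base core removed genes from the test and left 3268, 1674 higher and 1594 lower. An estimated correlation left 7 lists. For the TGF-beta, lung and airway lineage and histone lists, all lost, the estimates were -0.042, -0.043 and -0.021, under the preset 0.01. Closer correlation between their members therefore does not account for these losses, and no other cause was tested. Library totals without scaling gave 6138 genes, 55.5% of them higher. DESeq2 gave 5164 genes and no list test. The replicate block gave 5579 genes, 5515 of them shared with the fit without it. Libraries of like number gave correlations of deviations of 0.06, -0.11 and -0.09. No library correlated best with its own number, and the highest correlation was 0.21, between si-SNHG17 replicate 2 and si-NC replicate 3. The numbers were therefore not taken to pair the libraries. COL1A1, not past the threshold, ran from -0.0491 without si-SNHG17 replicate 2 to 0.1876 without si-NC replicate 3, with -0.0387 without si-NC replicate 2 and -0.1275 with the GC offset. CD79A ran from -0.0993 without si-NC replicate 1 to 1.1708 without si-NC replicate 3, with -0.0628 without si-NC replicate 2. The mean of the YAP/TAZ list ran from -0.0084 without si-NC replicate 3 to 0.0611 without si-NC replicate 1, and was -0.0070 with the GC offset; the causes were not tested. Of the values of other named genes and lists in the settings other than fry and the estimated correlation, 10 lost and 9 gained the threshold, and 2416 stayed on their side. Counts of 0 to 3 per library limit the snoRNAs and other rare RNAs.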

Other observations

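The tests of summed snRNAs and of the gene lists in the next paragraph were chosen only after the data were seen, as were the shares with other forms of the 7-base site, the GC and length offset, the share of higher calls with library totals, and the interval around the histone median, though not the limits it was held to; the others were fixed before the values they measure.

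A further 7 lists were drawn up after the ranking of genes had been seen, so their counts and p-values describe that ranking and are not independent evidence. Of 13 MHC class I presentation genes tested, 11 rose and none fell, with HLA-B (2.05), HLA-F (1.69), HLA-C (1.08) and B2M (0.81), and camera gave an adjusted p of 1.51e-11 but 0.071 with an estimated correlation. Reads of HLA genes can be shared between them. Of 14 fatty acid synthesis genes, 12 fell and 1 rose (adjusted p = 9.3e-14, and 0.0343 with an estimated correlation). Of 10 genes for liver-type secreted proteins, 7 fell and none rose (2.85e-08, and 0.0252), and of 10 genes for laminin-332 and hemidesmosomes 5 rose and 1 fell (3.14e-05, and 0.044). Of 47 nuclear-encoded respiratory chain genes, 30 fell and 1 rose (3.93e-09, but 0.134 with an estimated correlation). EGFR ligands did not pass (2 of 6 rose, 0.411), and 4 metallothioneins were too few for camera, of which 3 rose.

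Small structured RNAs were higher in the si-SNHG17 libraries: RMRP had 154, 197 and 193 counts against 14, 7 and 12, and RN7SL1 281, 383 and 374 against 61, 82 and 68. A preference for short mRNAs is argued against only for the 114 whose length was under 700 nt. Length was that of the longest annotated transcript, protein-coding where available, so the other 11881 mRNAs can include genes counted as shorter forms. Those 114 differed from the other mRNAs by 0.0139 on the log2 scale (standard error 0.0754), where at least 0.5 had been set. Annotated transcript length need not give insert length, so this cannot decide on a preference for short inserts. Nor can it decide for RNAs as short as RMRP (268 nt) and RN7SK (328 nt). Greater RNA polymerase III output as the whole cause is argued against by the polymerase II snRNAs U1, U2, U4 and U5, whose summed counts rose by 4.31 on the log2 scale (exact binomial interval 3.44 to 5.33, counting error only; 2.16 with pseudogene rows included). More RNA without a poly(A) tail in these libraries stays open. The histone median was 1.07, above the 1 set for it, but the interval over 9 genes ran from 0.08 to 1.54. The median cannot decide, since whether the histone mRNAs counted lacked a tail is not known. HIST2H2BE, HIST1H2BD and HIST1H2BC have annotated 3 prime UTRs of 1801, 384 and 272 nt, so forms with a tail may have been counted. Rows of other RNA without a tail moved little as classes, snoRNAs from 0.0519% to 0.0609% of counts and tRNAs from 0.0122% to 0.0134%. These shares speak against more RNA without a tail only as far as the reads come from the mature RNAs. Whether they came from host or mitochondrial transcripts instead was not tested.

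For the large falls of mRNAs, an siRNA off-target effect through seed matches in 3 prime UTRs is a candidate explanation. Of 16224 sites tested, CCTCTGT had the most negative score (-16.6, 2417 carriers, Bonferroni-adjusted p over the SNHG17 sites 1.49e-58), and it occurs in 7 of the 8 annotated SNHG17 transcripts; 20.4% of the sites tested occur in at least 1 of these transcripts. The share of mRNAs called lower was 39.4% with the 8-base site CCTCTGTA, 27.8% with CCTCTGT alone and 15.4% with none. Of the 10 largest falls, 5 carry CCTCTGT and 8 carry CCTCTGT or CTCTGTA. Neither CCTCTGTA nor CTCTGTA occurs in any of the 8 annotated SNHG17 transcripts. Direct matches to either 7-base site as the cause of most lower calls are argued against. Of the mRNAs called lower, 30.4% carry CCTCTGT (95% exact interval 28.6 to 32.3), 41.9% either 7-base site and 62.4% the 6-base core CTCTGT. These shares were 20.3%, 28.02% and 51.2% of all mRNAs searched and 14.9%, 20.3% and 45.0% of those called higher. Genes lowered downstream of such matches need carry no site, so the shares cannot decide on indirect effects of the siRNA. Among falls of at least 1 and 1.5 on the log2 scale, 54.7% and 60.2% carry either 7-base site, against 28.02% of all mRNAs searched. Unlike the site scores, the shares in this paragraph were not adjusted for UTR length or GC content. They use the longest annotated 3 prime UTR, and a longer UTR is likelier to carry any site. How many of the larger falls the off-target effect could account for stays open. So does loss of SNHG17 itself, untested because the design cannot part it from its siRNA.

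In all, 6112 genes passed the threshold, and a trend in GC content and transcript length is argued against as the whole cause: 6905 genes passed with an offset for both, and 5849 to 6682 when each library was left out. Displacement by a few abundant transcripts would shift the other genes together. With library totals only, which leave displacement in place, the median log2 fold change was 0.0452, against 0.0077 in the main fit. Any such shift was therefore small. With those totals 55.5% of the calls were higher (exact interval 54.3 to 56.8), under the 90% set for displacement after the data were seen. That share cannot decide, since so small a shift could hardly bring it to 90%. An earlier test without the 20 most abundant genes (6094 genes passed) was found void because TMM already removes displacement. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 split, the real one, reached 6112 genes (3057 higher, 3055 lower), and the highest other gave 1. For lists, 1 split reached the real 15, and the highest other gave 12, in a split with 1 gene past the threshold. Every other split set unequal numbers of si-SNHG17 and si-NC libraries against each other, so part of the treatment difference stayed in it. The rest of that difference widened the spread within each side. These splits therefore do not show how many genes or lists would be called without a difference. For the number of genes past the threshold, no biological explanation other than the siRNA treatment itself can be separated here, and none was tested.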
